A study of Homo sapiens with 3 samples.

How the data were processed

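The series held 3 arrays of HepG2 cells, 1 each of untreated cells and of cells exposed for 24 h to graphene oxide (GO) or reduced graphene oxide (rGO) at the EC20 of each material. Biotin-labelled cDNA made from total RNA was hybridised to Affymetrix arrays. The deposited values were log2 expression values for 33297 probe sets, and they spanned 2.17 to 14.5 with near-equal distributions in the 3 arrays. The submitters' processing notes name RMA and MAS5 without a role or version for either; the authors' log2 values look normalised between arrays, no gene was centred, and any further scaling is unknown. Median values were 6.65 (control), 6.63 (GO) and 6.66 (rGO). The genome build and annotation used by the authors are not given in the sources used here, and no coordinates are printed.

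Probe sets were joined to genes through the platform's probe annotation, which can be old. Of the probe sets, 19460 carried 1 gene symbol, 1754 several and 12083 none that was listed, and only those with 1 symbol were used for genes. A RefSeq gene table gave biotypes and gene order, with 19429 probe sets matched by Entrez ID and 0 symbols updated. The 18417 genes were represented by the probe set with the highest mean value, a choice that concerned 769 genes with more than 1. Genes whose mean over the 3 arrays reached the 40th percentile (log2 6.66) passed the level filter, which left 11050.

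Each comparison was a difference of log2 values between 2 arrays: GO minus control, rGO minus control and GO minus rGO. With 1 array per group no significance test exists, so genes were counted by a fixed size of 2-fold (log2 difference of 1). The gene lists, the genes to be named, the filter, the size and the alternatives were chosen before the data were examined. The rule named the 12 highest and 12 lowest genes of each comparison, leaving out uncharacterised loci, olfactory receptors, LINC genes and small RNAs by symbol prefix (snoRNA, scaRNA, microRNA, snRNA, Y RNA and tRNA genes, but not vault RNAs), the 3 members of each list with the largest difference from control, and up to 10 genes past 2-fold in both exposures, of which there were 0. Not all of these genes are printed. Other list members are printed as examples picked after their values were seen, some with the list's direction and some near 0 or against it. The 42 gene lists covered stress responses, metabolism, liver functions, immunity, adhesion, cell cycle, organelles and markers of other cell types.

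A list's median was placed as a percentile among the medians of 10000 random lists of the same size, drawn from 20 bins of expression level. Lists at or under the 2nd or at or over the 98th percentile were said to stand apart; this describes a list's place and is no test, since genes of a list are correlated. The leukocyte list, with fewer than 5 genes past the filter, got values only. The robust SD is the scaled median absolute deviation. Pairs of probe sets of the same gene, both past the filter, disagreed with a robust SD of 0.0804 in the GO comparison and 0.0539 in the rGO comparison (365 genes, each divided by the root of 2), after 66 genes whose probe sets held identical values were left out. Whether the remaining pairs share probes was not checked, and pairs that do would make these SDs understate the technical spread.

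The effect of the shared control was gauged from 100 simulated sets of 3 unchanged arrays. The size rule and the percentile were tested on simulated data for 1 exposed array minus 1 control array with 11050 genes, whose noise followed the rGO comparison. The rule called 0% of 70 genes changed 1.5-fold, 48.3% of 60 changed 2-fold, 100% of 70 changed 4-fold and 0% of 10850 unchanged genes. Of 100 unchanged lists of 20 genes 7% were said to stand apart, and of 50 lists shifted by 0.1 log2 84% were found. The GO comparison had a wider robust SD, 0.244 against 0.116, so none of these shares gives an error rate for its calls.

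Alternatives were quantile normalization, median centring, a loess (span 0.3) on the mean level, no level filter, a 60th percentile filter, a filter on the higher of the 2 arrays compared, the mean of a gene's probe sets, thresholds of 1.5-fold and 3-fold, and list means in place of medians. The 1.5-fold overlap and counts of protein-coding genes alone were added after the data had been seen. Gene neighbourhoods used the 10 nearest measured genes, 5 on each side, in RefSeq order. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Probe sets without a single gene name were left out of the gene comparisons and are counted in the closing section.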

Results

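Gene expression was measured in HepG2 cells, an established human liver tumour line, on 3 Affymetrix arrays: 1 of untreated cells, 1 of cells exposed to graphene oxide (GO) and 1 of cells exposed to reduced graphene oxide (rGO), a form of the material with fewer oxygen groups. Each exposure lasted 24 h at its own EC20, the dose that a viability assay linked to a 20% effect. The labels give no concentrations, so the doses of GO and rGO may differ and cannot be set side by side. Each array held log2 values for 33297 probe sets, with medians of 6.65 in the control, 6.63 in the GO array and 6.66 in the rGO array. Across all probe sets Pearson's r was 0.991 between GO and control, 0.995 between rGO and control and 0.991 between GO and rGO. No group had replicates, so every value is a difference between 2 single arrays without an error, no test was run, and the number of arrays limits the precision.

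The first comparison asked how GO-exposed cells differed from untreated cells. The inhibitors of differentiation ID1 and ID3, transcriptional regulators that act downstream of BMP signals, were 7.39-fold and 6.51-fold lower with GO (log2 differences -2.88 and -2.70). The GO value of ID3, 6.49, lay under the filter level of 6.66, where background can hide signal, so its fold can be understated. HAMP, which encodes the iron hormone hepcidin, was 6.56-fold lower, and the glutathione transferase GSTA1 was 5.62-fold lower. IGFBP1, a secreted binder of insulin-like growth factors, was 3.97-fold higher, and BHLHE40, a hypoxia-inducible repressor of transcription, was 2.88-fold higher. Genes of glycolysis and hypoxia, of the cytoskeleton and of the YAP pathway were higher as groups, whereas metallothioneins, conjugating enzymes, mitotic genes, heat shock proteins and cholesterol synthesis genes were lower. Of 11050 genes past the level filter, 28 were at least 2-fold higher and 101 at least 2-fold lower in the GO array, and all 129 were protein-coding.

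The 12 highest genes after GO also included TMC7, of a family of transmembrane channel-like proteins (1.46), and CHST15, which sulphates chondroitin (1.44). AGR2, a disulphide isomerase of the endoplasmic reticulum, stood at 1.44 from a control value of 6.23 under the filter level, and CEMIP, which takes part in the breakdown of hyaluronan, at 1.38. MATN3, a cartilage matrix protein, was higher by 1.30, the mannosyltransferase PIGZ by 1.28 and the amino acid transporter SLC43A2 by 1.24. AKAP12, a scaffold for protein kinase A, was higher by 1.23 and MAML2, a coactivator of Notch signalling, by 1.19. KRTAP3-1, a hair keratin-associated protein, stood at 1.44, with its probe set listed at 2 positions holding identical values.

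Among the 12 lowest genes, the metallothionein MT1M stood at -2.30, and the aldo-keto reductases AKR1B10 and AKR1C2 stood at -1.99 and -1.65. PFDN4, a subunit of the prefoldin chaperone, was lower with a difference of -1.98. The centromere proteins CENPQ and ITGB3BP stood at -1.58 and -1.48, and HAUS1, of the augmin complex of the mitotic spindle, at -1.50. RIDA, an enzyme that removes reactive imines, stood at -1.46. MT1M, GSTA1 and AKR1C2 belong to families of near-identical copies, so a probe set can read more than 1 member and the values of single members are uncertain.

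**Figure D1:**
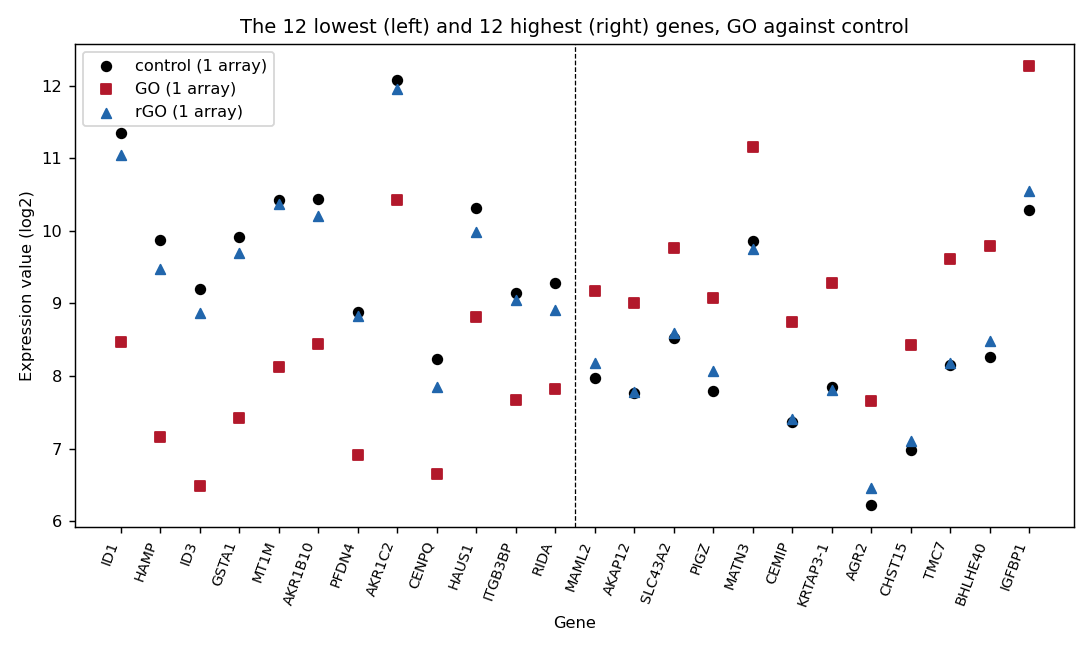
Log2 expression values (vertical axis) of the 12 lowest and 12 highest genes of the GO comparison (horizontal axis) in the control, GO and rGO arrays, with 1 point per array. ID1 stood at 11.35 in the control, 8.46 in the GO array and 11.04 in the rGO array.

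Gene lists fixed before the data were examined were placed by their median difference among 10000 random lists matched on expression level, and 14 of the 41 lists with enough genes lay at or beyond the 2nd or 98th percentile after GO, where 1.64 would be met if genes were independent. Of 23 hypoxia and glycolysis genes, 22 were above 0 and 4 were at least 2-fold higher, with a median of 0.43 (percentile 100). The 4 were BHLHE40, the glucose transporter SLC2A3 (1.11), hexokinase HK2 (1.09) and PFKFB4 (1.04), a regulator of the glycolytic rate. ALDOC stood at 0.98 and PDK1, which restrains pyruvate oxidation, at 0.76, while VEGFA and ADM stood at 0.21 and 0.15. With no level filter the list's median was 0.34.

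All 25 measured cytoskeleton and adhesion genes were above 0, with a median of 0.42 (percentile 100) and 1 gene at least 2-fold higher. These included the actin binder TAGLN2 (1.07), the keratins KRT19 (0.79), KRT23 (0.75) and KRT18 (0.73), and the non-muscle myosin MYH9 (0.64). All 10 KRT genes past the filter, listed or not, had a median of 0.03 with 6 above 0 and 4 below (percentile 67.77). Of 13 YAP targets, genes driven by the Hippo pathway's effector, 12 were above 0 with a median of 0.32 (percentile 99.99) and 0 at least 2-fold higher. CCN1 stood at 0.97, CCN2 at 0.80 and ANKRD1 at -0.23. Extracellular matrix and epithelial-mesenchymal transition genes had a median of 0.44 over 11 genes, 9 of them above 0 (percentile 100). CDH1, the epithelial cadherin, stood at 0.996, the lysyl oxidase LOX at 0.77, and the metalloproteinase inhibitors TIMP1 and TIMP2 at 0.87 and 0.69. As fixed, the list pools the epithelial CDH1 with mesenchymal genes such as VIM, so its median gives no direction of a transition. This last list lost its place with no level filter, where the median over its 26 measured genes was -0.0019 (percentile 59.61). The 18 collagen (COL) genes past the filter went mostly the other way, with a median of -0.08, 3 above 0 and 15 below (percentile 8.21).

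Of 21 immediate early genes, which respond first to growth factors and stress, 16 were above 0 and 1 was at least 2-fold higher, with a median of 0.23 (percentile 99.95). EGR1 stood at 1.10, IER3 at 0.75 and FOSL2 at 0.74, while FOS and MYC stood at -0.11 and -0.07. Viral entry receptors, mostly adhesion and membrane proteins, had a median of 0.24, with 13 of 15 above 0 (percentile 99.92) and 0 past 2-fold. The integrin subunit ITGB5 stood at 0.70, the tetraspanin CD9 at 0.49 and the adhesion molecule NECTIN2 at 0.44. Hepatocyte secreted proteins had a median of 0.12, with 15 of 23 above 0 (percentile 98.18, and 96.95 after quantile normalization). The apolipoprotein gene APOM stood at 0.87, VTN at 0.78 and TTR at 0.70, while ALB, which encodes albumin, stood at -0.01 and SERPINC1, the gene of antithrombin, at -0.59.

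Metallothioneins and metal response genes had a median of -0.39, with 11 of 14 below 0 and 4 at least 2-fold lower (percentile 0.01). The 4 were MT1M, MT1F (-1.40), MT1G (-1.22) and MT1X (-1.03), while MT2A stood at -0.19 and the zinc importer SLC39A10 at 0.80. Conjugating enzymes and export transporters had a median of -0.30, with 17 of 20 below 0 (percentile 0.00) and 3 at least 2-fold lower. These were GSTA1, GSTA2 (-1.44) and the oestrogen sulphotransferase SULT1E1 (-1.15). GSTA2 and SULT1E1 stood at 6.23 and 6.21 in the GO array, under the filter level, so their differences can be understated too. NRF2 targets, genes of the antioxidant response, had a median of -0.20 with 16 of 19 below 0 and 2 at least 2-fold lower (percentile 0.79). AKR1C1 stood at -1.03 and thioredoxin TXN at -0.73. HMOX1, the haem oxygenase, stood at -0.08 and the cystine transporter SLC7A11 at 0.23. AKR1C1 stood at -0.54 when its 2 probe sets were averaged, because the weaker one stood at -0.05.

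Of 29 G2/M and mitosis genes, 24 were below 0 and 3 were at least 2-fold lower, with a median of -0.37 (percentile 0.00). The kinetochore motor CENPE stood at -1.34, the spindle protein HMMR at -1.33 and the kinase CDK1 at -1.09. Within the same list PLK1 stood at 0.13, AURKB at 0.05, UBE2C at -0.01 and MKI67 at 0.27. G1/S and DNA replication genes had a median of -0.09 with 17 of 29 below 0 (percentile 5.92). RFC4, a subunit of the clamp loader, stood at -0.997, POLE2 at -0.72 and CCNE2 at -0.52. DNA repair genes had a median of -0.12 with 19 of 29 below 0 (percentile 2.04), including the end-joining factor XRCC4 at -1.19, the base excision polymerase POLB at -1.14 and RAD50 at -0.81. The repair list lay under the 2nd percentile in other settings, at 1.37 with the probe sets of a gene averaged.

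Heat shock genes had a median of -0.28 with 8 of 12 below 0 (percentile 0.48) and 0 at least 2-fold lower. The mitochondrial co-chaperone HSPE1 stood at -0.65, HSPA4L at -0.60 and HSP90AA1 at -0.59, whereas the small heat shock protein HSPB1 stood at 0.41. Of 18 cholesterol synthesis genes, 15 were below 0 with a median of -0.24 (percentile 0.25). The isomerase IDI1 stood at -1.30, the only member at least 2-fold lower, with ACAT2 at -0.77 and HMGCS1 at -0.64. Of 32 oxidative phosphorylation genes, 25 were below 0 with a median of -0.23 (percentile 0.02). The complex I subunits NDUFB3 and NDUFA2 stood at -1.34 and -0.78 and the ATP synthase subunit ATP5F1C at -0.74, while NDUFV1 stood at 0.26 and UQCRC1 at 0.24. Listed or not, the 12 NDUFA genes past the filter had a median of 0.05, with 7 above 0 and 5 below. The 11 NDUFB genes had one of -0.17, with 2 above 0 and 9 below.

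TGF-beta signalling genes split, with a median of 0.10 (percentile 95.75) and a mean of the opposite sign, -0.09. The 4 genes at least 2-fold lower were ID1, ID3, ID2 (-1.38) and the inhibitory SMAD7 (-1.06). On the higher side CCN1 stood at 0.97, the co-receptor TGFBR3 at 0.86, TGFB1 at 0.84 and SMAD3 at 0.63. Iron handling genes had a median of -0.11 (percentile 15.51), and beyond HAMP the transferrin receptor TFRC stood at 0.35 and SLC11A2 at -0.23. Acute phase proteins had a median of -0.01 (percentile 44.34), with the fibrinogen chain gene FGB at -0.85 and ceruloplasmin CP at 0.78. Bile acid genes had a median of -0.05 (percentile 30.00), with the transporter subunit SLC51B at -1.36 and SLC51A at 0.48. The gluconeogenesis and amino acid catabolism list had a median of 0.15 (percentile 95.58). Its 1 member at least 2-fold higher was IGFBP1, a secreted binding protein and not an enzyme of either pathway.

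The p53 targets had a median of -0.02 (percentile 31.23), with CCNG1 at -0.51, PPM1D at -0.48 and CDKN1A, the cell cycle inhibitor p21, at 0.12. Apoptosis regulators had a median of 0.03 (percentile 68.30), with BIRC2 at -0.53, TNFRSF10D at 0.47 and CYCS at -0.37. The ATF4 and CHOP list had a median of 0.00 (percentile 48.47), with GDF15 at 0.54, CEBPG at -0.53 and STC2 at 0.41. Endoplasmic reticulum chaperones had a median of 0.02 (percentile 58.94), with EDEM1 at 0.53, SYVN1 at 0.41 and HSPA5 at 0.07. Peroxide and superoxide detoxification genes had a median of -0.13 (percentile 6.13), with GPX7 at -0.58, GPX1 at -0.54 (-0.34 with its 2 probe sets averaged) and SOD2 at 0.41. NADPH oxidase subunits had a median of 0.09 over 5 genes (percentile 78.17), with CYBA and RAC1 both at 0.42.

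Toll-like receptor and NF-kappa-B components had a median of 0.10 (percentile 92.34), with CHUK at -0.65 and RELA at 0.56. Cytokines and chemokines had a median of 0.16 over 9 genes (percentile 92.97), with the chemokine CCL16 at 1.09 and CSF1 at 0.64, while CXCL8 stood at 0.10. Interferon-stimulated genes had a median of 0.00 (percentile 44.55), with IFITM2 at 0.79, IFITM3 at 0.60 and IFIH1 at -0.58. Antigen processing genes had a median of -0.09 (percentile 12.02), with PSME2 at -0.61. Complement and coagulation genes had a median of 0.02 and a mean of -0.01 (percentile 60.73), with MBL2 at 0.67 and PLG at 0.56. Fatty acid oxidation genes had a median of 0.00 (percentile 46.43), with the pantetheinase VNN1 at 0.98, CPT1A at 0.73 and ACADM at -0.65. Fatty acid synthesis genes had a median of 0.01 and a mean of -0.10 (percentile 49.61), with the acyltransferase GPAM at -1.01 and DGAT1 at -0.69. Cytochrome P450 genes had a median of -0.13 (percentile 5.43), with CYP3A43 at -0.94 and CYP2J2 at 0.76.

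Hepatocyte transcription factors had a median of 0.08 (percentile 81.83), with CEBPA at -0.55. Autophagy and lysosome genes had a median of 0.12 (percentile 97.85), with ATG3 at -0.78, ATG5 at -0.55 and WIPI1 at 0.49. Endocytosis and scavenger receptors had a median of 0.06 (percentile 79.38), with CAVIN1 and CLTB both at 0.68. Replication-dependent histones had a median of 0.10 (percentile 94.66), and cytosolic ribosomal proteins a median of -0.02 (percentile 39.60) with RPL7 at -0.83. The histones are a family of near-identical copies. Markers of other cell types were set beside these groups: 4 leukocyte genes had a median of 0.09, and 5 fibroblast, stellate and endothelial genes a median of 0.13 (percentile 89.03).

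Differences between GO and control had a robust SD of 0.244 among genes past the level filter and 0.186 among the 7367 weakly expressed genes below it. CENPQ and CYP3A43 in the GO array and CYP2J2 in the control also lay under the filter level. Both robust SDs mix variation between 2 dishes of cells and their arrays with any effect of GO, and without replicates these parts cannot be separated. None of the differences can therefore be told from variation between dishes.

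The second comparison asked how rGO-exposed cells differed from untreated cells, and the differences were small. The vault RNA VTRNA1-2, a short noncoding RNA, was 2.53-fold lower (-1.34), and the spliceosomal RNA RNU5B-1 was 2.09-fold lower (-1.07). These were the only 2 genes at least 2-fold lower, RNU5B-1 being named after its value was seen, and 0 were at least 2-fold higher. At 1.5-fold, 3 genes were higher and 14 lower, with 1 protein-coding gene among the 3 and 0 among the 14. The other vault RNAs, VTRNA1-1 and VTRNA1-3, both stood at -0.79. As near-identical copies, the vault RNAs can share signal between their probe sets.

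The highest genes after rGO were the noncoding PRDM16-DT (0.72), the bitter taste receptor TAS2R19 (0.66), SND1-IT1 (0.56), the p53 regulator MDM4 (0.55) and EMC3-AS1 (0.54). They were followed by HAL, which degrades histidine (0.48), CRACR2A (0.47), FAM86B2-DT (0.47), CHP1P2 (0.45), PLEKHH2 (0.45), TAS2R4 (0.45) and FOXJ1 (0.44), a regulator of motile cilia. Below control, apart from the vault RNAs and the small RNA classes that the naming rule left out, were SSTR5-AS1 (-0.83), GPAT2P2 (-0.69), GLP2R (-0.58), SCX (-0.57), CYP1A1 (-0.52), TRIM50 (-0.52), CSH2 (-0.51), S100A3 (-0.50) and RAB13 (-0.49). CYP1A1 is the main enzyme induced through the aryl hydrocarbon receptor. With their 2 probe sets averaged PRDM16-DT stood at 0.38 and RAB13 at -0.26, and CRACR2A stood at 0.18, under the level filter, with its 3 averaged. TAS2R19, HAL and FOXJ1 in the control and RNU5B-1, SCX and CSH2 in the rGO array lay under the filter level, where background can distort a difference.

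Of 18 cholesterol synthesis genes, 17 were above 0 after rGO, with a median of 0.11 (percentile 99.98). HMGCS1 stood at 0.23, LSS at 0.18 and IDI1, the exception, at -0.24. Fatty acid synthesis genes had a median of 0.09 with 14 of 17 above 0 (percentile 99.83), with the desaturase FADS2 at 0.35, MLXIPL at 0.29 and FASN at 0.24. Hepatocyte secreted proteins had a median of 0.07 with 19 of 23 above 0 (percentile 99.94), with APOM at 0.30 and ALB at 0.07. Cytoskeleton genes had a median of 0.06 with 17 of 25 above 0 (percentile 99.30), and G1/S genes a median of 0.04 with 22 of 29 above 0 (percentile 98.17, and 96.53 after quantile normalization).

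Oxidative phosphorylation genes had a median of -0.09 after rGO, with 28 of 32 below 0 (percentile 0.00). COXFA4 stood at -0.24, NDUFB3 at -0.22 and NDUFA1 at -0.21. The p53 targets had a median of -0.10 with 20 of 22 below 0 (percentile 0.19), with PPM1D and TP53I3 both at -0.24 and CDKN1A at -0.11. The 2 above 0 were MDM2 at 0.18 and XPC at 0.19. Conjugating enzymes had a median of -0.08 with 16 of 20 below 0 (percentile 1.59, and 3.34 with probe sets averaged), with GSTA2 at -0.26 and GSTA1 at -0.23. The medians of metallothioneins (-0.04), NRF2 targets (-0.05), heat shock genes (0.01), hypoxia and glycolysis genes (0.01), YAP targets (0.01), immediate early genes (-0.04) and G2/M genes (0.04) lay between the 2nd and 98th percentiles. The 8 lists beyond those percentiles stand against 1.64 if genes were independent, and 0 of their members differed by 1.5-fold. Oxidative phosphorylation (-0.23) and conjugating enzymes (-0.30) also stood apart as lower after GO. Hepatocyte secreted proteins (0.12) and cytoskeleton genes (0.42) stood apart as higher in that comparison too. Both comparisons share the 1 control array, whose own deviation could shift these lists the same way, and this cannot be split off from an effect of rGO.

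Medians after rGO lay between the same percentiles for DNA repair (0.03), apoptosis regulators (-0.04), the ATF4 and CHOP list (0.04), endoplasmic reticulum chaperones (0.01), peroxide detoxification (-0.02), NADPH oxidase subunits (0.02) and iron handling (-0.08). The same held for bile acid genes (-0.03), Toll-like receptor components (-0.02), cytokines (-0.01), interferon-stimulated genes (-0.02), viral entry receptors (-0.01), antigen processing (-0.03), acute phase proteins (-0.02) and complement (-0.01). It held too for TGF-beta genes (-0.04), matrix genes (0.01), histones (-0.01), ribosomal proteins (-0.03), gluconeogenesis (-0.05), autophagy (-0.01), endocytosis (0.03), fatty acid oxidation (-0.05), hepatocyte transcription factors (-0.03) and cytochrome P450 genes (0.09). The P450 list's mean was -0.01, of the opposite sign, as was the YAP list's mean of -0.01 and the histones' mean of 0.0046. Leukocyte markers had a median of 0.01 and fibroblast, stellate and endothelial markers a median of -0.17 (percentile 2.29), with LYVE1 at -0.45 and PDGFRB at -0.40. In the rGO array LYVE1 (6.59) and PDGFRB (6.57) lay under the filter level, where background can distort a difference. Differences between rGO and control had a robust SD of 0.116 past the level filter and 0.165 below it.

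**Figure D2:**
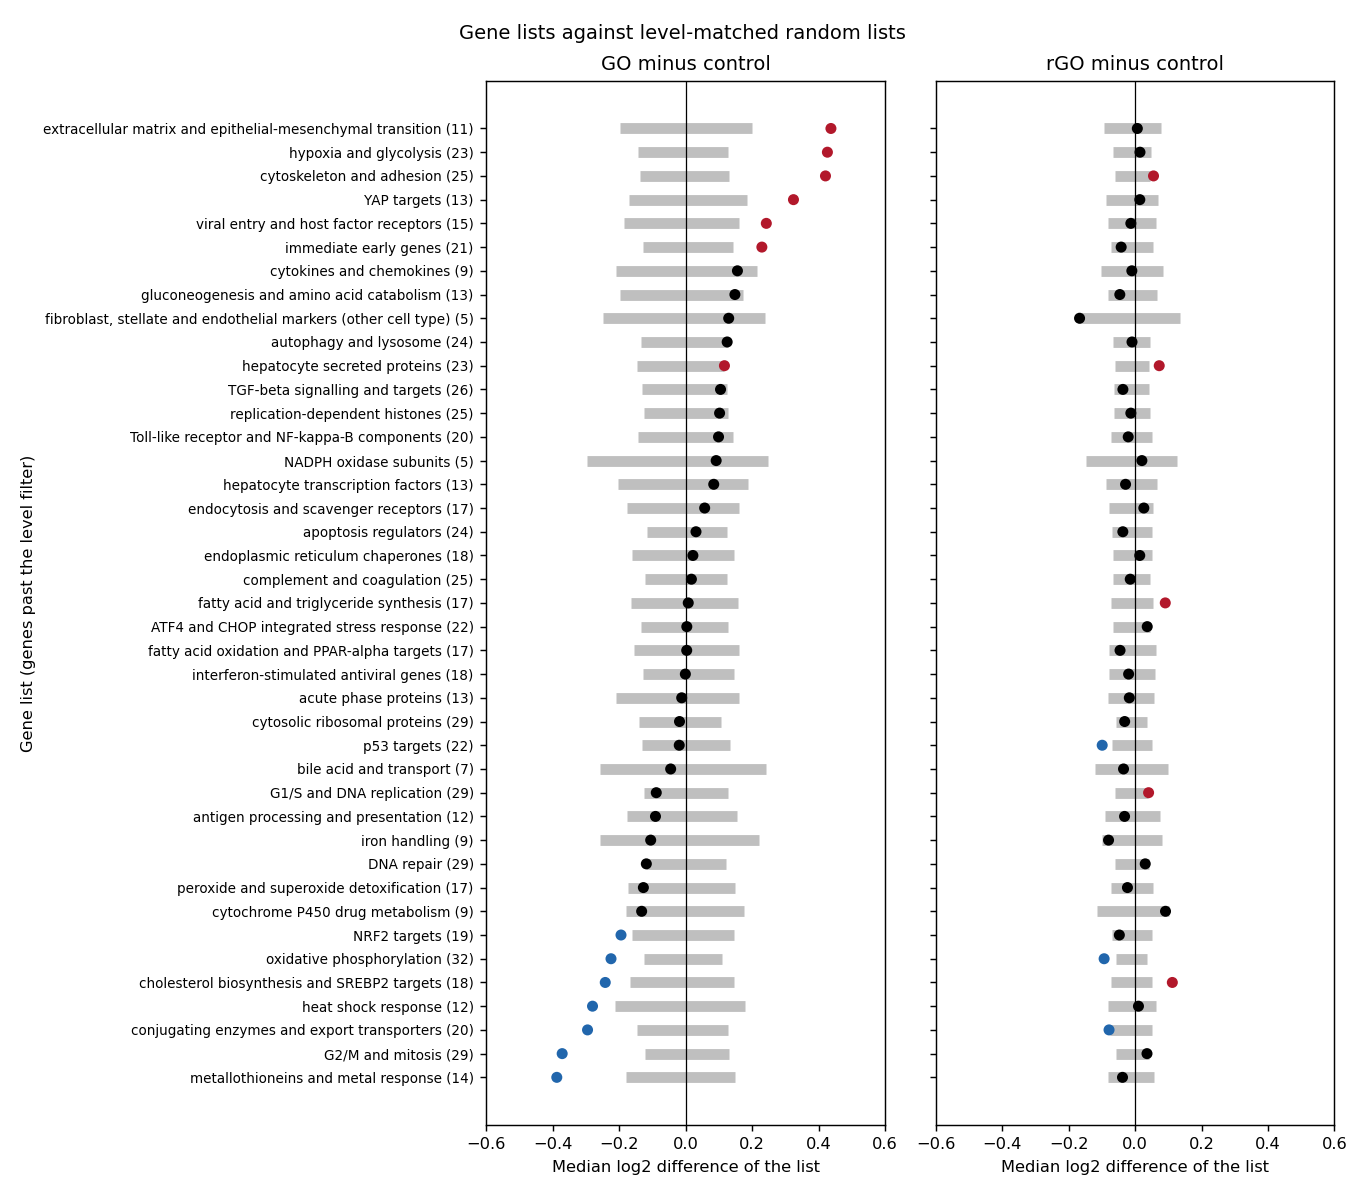
Median log2 difference of each gene list (horizontal axis) for GO and rGO against control, with the number of genes past the level filter in brackets; grey bars span the 2nd to 98th percentiles of 10000 level-matched random lists. Red points lay at or above the 98th percentile, blue points at or below the 2nd and black points between them.

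The third comparison set the GO array directly against the rGO array. IGFBP1 was 3.30-fold higher with GO than with rGO (1.72), and FSTL3, an inhibitor of activins, was 2.87-fold higher (1.52). ID1 was 5.95-fold lower (-2.57), ID3 5.22-fold lower (-2.38) and HAMP 4.99-fold lower (-2.32). In all, 29 genes were at least 2-fold higher and 59 at least 2-fold lower, of which 26 and 58 were protein-coding. Of the 129 genes at least 2-fold from control after GO, 22 of the 28 higher and 54 of the 101 lower also differed by 2-fold from the rGO array. Both differences hold the same GO array and the genes were picked on its value, so these counts are no independent evidence of a difference between the exposures.

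The genes highest against rGO continued with KRTAP3-1 (1.48), TMC7 (1.44), VNN1 (1.41), MATN3 (1.41), CEMIP (1.34), CHST15 (1.32), VTRNA1-1 (1.31), BHLHE40 (1.30), AKAP12 (1.23) and the tight junction gene CLDN6 (1.22). Those lowest continued with GSTA1 (-2.26), MT1M (-2.24), PFDN4 (-1.92), AKR1B10 (-1.76), AKR1C2 (-1.52) and HMMR (-1.39). IFT74, of the ciliary transport machinery, stood at -1.39, the nucleolar protein MPHOSPH10 at -1.37 and ITGB3BP at -1.37. IFT74 in the GO array (5.99) and VNN1 in the rGO array (6.63) lay under the filter level. VNN1 and FSTL3 were above control after GO (0.98 and 1.18) and below it after rGO (-0.43 and -0.34).

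Of the 41 lists, 18 lay beyond the 2nd or 98th percentile between GO and rGO, 9 on each side. The higher lists were YAP targets (0.41), matrix genes (0.41), cytoskeleton (0.38), cytokines and chemokines (0.37), hypoxia and glycolysis (0.36), immediate early genes (0.30), viral entry receptors (0.27), Toll-like receptor components (0.16) and apoptosis regulators (0.13). The lower lists were G2/M genes (-0.37), metallothioneins (-0.36), cholesterol synthesis (-0.35), heat shock genes (-0.33), conjugating enzymes (-0.25), NRF2 targets (-0.21), DNA repair (-0.21), oxidative phosphorylation (-0.13) and G1/S genes (-0.13). The cytokine list held 9 genes, 8 of them above 0, and its median was 0.10 (percentile 97.72) with no level filter, where the matrix list's was 0.06 (percentile 87.93). The apoptosis list had a median of 0.07 (percentile 78.60) and the Toll-like receptor list a median of 0.13 (percentile 95.45) under the stricter level filter. Median and mean differed in sign for TGF-beta genes (0.10 and -0.05), P450 genes (0.02 and -0.03), acute phase proteins (0.0048 and -0.20) and endoplasmic reticulum chaperones (-0.01 and 0.03).

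The differences of GO and of rGO from control were also set against each other across genes. Of the 28 genes at least 2-fold higher after GO, such as IGFBP1 and BHLHE40, 21 were above 0 after rGO, with a median of 0.08. Of the 101 at least 2-fold lower, such as ID1 and HAMP, 92 were below 0 after rGO, with a median of -0.14. These shares of 75.0% and 91.1% stand against 94.5% (range 78.6 to 100) and 92.4% (range 87.1 to 98) for equally many extreme genes in simulated arrays without any effect that share their control. The share for higher genes thus lay below the simulated range and that for lower genes inside it. No gene passed 2-fold in both, where 0.018 shared lower genes would be met if the comparisons were independent. At 1.5-fold PRDM16-DT was the 1 shared higher gene against 0.057, with 0 shared lower genes against 0.592, but comparisons that share a control are not independent, so these are not the counts of a no-effect case. With its 2 probe sets averaged PRDM16-DT stood at 0.34 after GO and 0.38 after rGO, under 1.5-fold in both. Across the 11050 genes, which are not independent replicates, Pearson's r was 0.385, Spearman's rho 0.411 and the covariance 0.0156. Simulated arrays without any effect, sharing their control as these do, gave an r of 0.50 (range 0.485 to 0.520) and a covariance of 0.0069 (range 0.0066 to 0.0074), so the observed r lay below the simulated range and the observed covariance above it. The share of genes with the same sign was 64.6%, below the 66.6% (range 65.5 to 67.4) of the simulation. The simulated noise followed the rGO comparison alone and was equal in the 3 arrays. Observed GO differences were wider, with a robust SD of 0.244 against 0.116 for rGO, so the simulation did not match the GO array. A place inside or outside a simulated range therefore shows neither shared nor opposite effects. Part of the likeness may come from the shared control, and with 1 control array it cannot be split off.

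**Figure D3:**
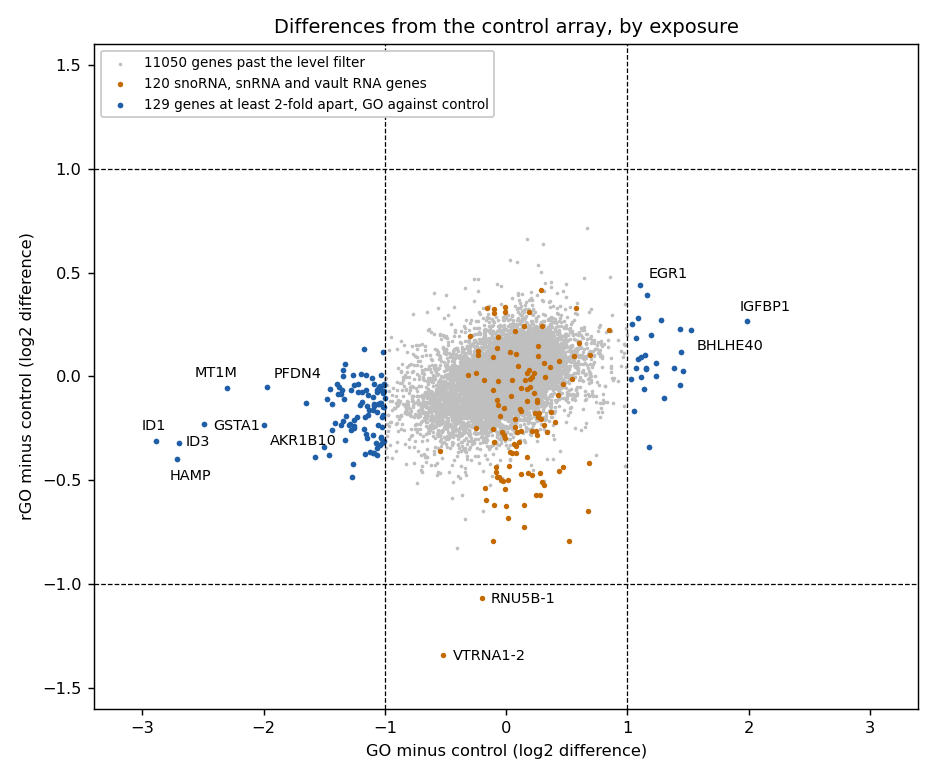
Log2 difference from control for 11050 genes with GO (horizontal axis) and rGO (vertical axis), 1 point per gene, with dashed lines at 2-fold. Among the 129 genes at least 2-fold from control after GO, the largest distance from the control after rGO was 0.48 log2.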

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

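The split of unnamed probe sets by number was chosen only after the result was seen. The cholesterol synthesis list stood apart in opposite directions, with a median of -0.24 (percentile 0.25) after GO and 0.11 (percentile 99.98) after rGO. HMGCS1, which feeds the mevalonate pathway, stood at -0.64 and 0.23, the lanosterol synthase LSS at -0.54 and 0.18, and the squalene epoxidase SQLE at -0.56 and 0.04. Not every member went opposite ways: IDI1 stood at -1.30 and -0.24, below control in both, while DHCR7 (0.28 and 0.17), PMVK (0.28 and 0.02) and the regulator SREBF2 (0.26 and 0.14) stood above it in both. Between the GO and rGO arrays the list's median was -0.35, with 15 of 18 genes below 0. The difference between the exposures was not tested, as each stands on 1 array.

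Probe sets without a single gene name were outside the comparisons, and 4925 of them passed the level filter. Of these, 11 were at least 2-fold higher than control in the GO array and 25 in the rGO array, against 39 and 2 at least 2-fold lower. Of the 25 in the rGO array, 24 belonged to the 2198 probe sets numbered before the first annotated one, whose rGO differences had a robust SD of 0.243 against 0.156 for the other 2727. Whether these 2198 probe sets read transcripts or are control features is not known here, so the 24 are not shown to be transcripts that rose.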

How the results depend on the processing

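The overlap at 1.5-fold and the counts of protein-coding genes were chosen only after the results were seen. Counts of genes followed the fold threshold: at 1.5-fold 211 genes were higher and 467 lower after GO, 3 higher and 14 lower after rGO, and 201 higher and 354 lower between GO and rGO; at 3-fold these counts were 1 and 8 after GO, 0 lower after rGO, and 1 and 7 between them. The rGO count of 2 lower genes was 4 with no level filter, 1 with the 60th percentile filter and 0 among protein-coding genes, because the filters change which genes are counted. The correlation of both differences was 0.401 with no level filter and 0.410 with the 60th percentile filter, from other sets of genes. The matrix list reversed after GO to -0.0019 with no level filter, as weakly expressed members came in. Of 1008 recomputed list medians, 937 moved by less than the SD of random lists, and of 3402 values of named genes, 3394 by less than the robust SD. The level filters leave a gene's own value as it is, and averaging changes only genes with more than 1 probe set. Much of the count for named genes was thus fixed in advance. Of the lists standing apart, 12 of 14 after GO, 6 of 8 after rGO and 14 of 18 between GO and rGO did so under all normalizations, filters and probe set choices. Those lost somewhere were matrix genes and hepatocyte secreted proteins after GO, G1/S genes and conjugating enzymes after rGO, and Toll-like receptor components, apoptosis regulators, cytokines and matrix genes between them. Lists that stood apart under some alternatives alone were DNA repair, TGF-beta genes, gluconeogenesis and histones after GO, P450 genes, iron handling and fibroblast markers after rGO, and interferon-stimulated, TGF-beta, gluconeogenesis, antigen processing and histone genes between them. The settings meant for linear values were not run, since the values were log2 already. Signal over background limits weakly expressed genes, and no sample could be left out.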

Other observations

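The tests of fewer cycling cells and of short RNA yield were chosen only after the results were seen. The single genes of this paragraph were also picked after their values were seen, and they stand for no group. Outside the fixed lists, ICAM1, a ligand for leukocyte integrins, stood at 1.15 after GO, the neural adhesion molecule L1CAM at 1.15, the integrin subunit ITGA2 at 1.07 and the focal adhesion gene TNS4 at 1.03. FILIP1L stood at 1.15 and DEPP1, a target of FOXO factors, at 1.13. The kinetochore gene NUF2 stood at -1.43, CENPK at -1.34 and the kinesin KIF20B at -1.18, while the 28 KIF genes had a median of -0.09 (percentile 4.46). The proteasome subunits PSMA3 and PSMA4 stood at -1.20 and -1.18, while the PSMB and PSMD families of the same complex had medians of -0.07 (percentile 22.31) and 0.05 (percentile 73.81). ALDH1A1, which makes retinoic acid, stood at -1.13, and CYP24A1, which inactivates vitamin D, at -1.09.

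Families sharing a symbol stem were scanned, 125 in all. After GO, 14 lay at or under the 2nd percentile and 8 at or over the 98th, against 2.5 on each side if genes were independent. After rGO these counts were 12 and 3, and between GO and rGO 17 and 11. Mitochondrial ribosomal MRPL genes had a median of -0.21 with 37 of 48 below 0, while the MRPS genes of the small subunit had one of -0.10 (percentile 6.76). Zinc finger ZNF genes had a median of -0.11 with 211 of 306 below 0 and centrosomal CEP genes a median of -0.20 with 19 of 27 below 0. KLF transcription factors had a median of 0.21 with 9 of 13 above 0. After rGO the MRPL genes had a median of -0.05 with 36 of 48 below 0, the MRPS genes one of -0.02 (percentile 34.78) and the COQ genes of ubiquinone synthesis a median of -0.13 with 10 of 11 below 0. The MRPL genes were thus lower in both comparisons, which share the control array. Neighbouring genes had correlated differences after GO (r 0.151 over 11017 adjacent pairs) and less so after rGO (0.0464).

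In the first pattern weighed, ID1, ID2, ID3 and HAMP, known targets of BMP signals, stood between -2.88 and -1.38 after GO. A shift of their chromosomal regions is argued against, since the lowest of the 4 medians over their neighbours was -0.0467 (spread 0.318). Lower BMP signalling stays open as a hypothesis. A list of 6 further targets, SMAD6, SMAD7, SMAD9, ATOH8, BAMBI and ID4, was drawn up after the pattern was seen. These had a median of -0.30 with 5 of 6 below 0, at percentile 0.65 of level-matched lists, which is no independent check. SMAD7 stood at -1.06 and BAMBI at -0.40, while ATOH8 and ID4, both under the level filter, stood at 0.17 and -0.23, and SMAD6, SMAD7 and BAMBI also belong to the TGF-beta list. The same targets had a median of -0.07 after rGO (percentile 16.40), and variation between cultures may also account for the pattern.

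In the second, the G2/M and mitosis list was lower after GO. Its percentile stayed at 0.00 after each gene's neighbours were subtracted (median -0.36), a correction whose sizes over all genes had a robust SD of 0.124, which argues against a regional shift as the whole cause. Fewer cycling cells could lower the list, but the G1/S list, at percentile 5.92 with a median of -0.09, neither joined it past the 2nd percentile nor reached 0, so this cannot be told apart from an effect on mitotic genes alone. CENPE, HMMR and CDK1 were low while AURKA (0.04), AURKB (0.05), PLK1 (0.13) and MKI67 (0.27) were not. Base composition or length of the transcripts, which was not tested here, and a change of the cell cycle by GO stay open. Composition and length are equally untested for the other lists, families and single genes that differed after GO.

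In the third, small structured RNAs were lower after rGO, with a median of -0.13 for 106 snoRNA genes, 72 of them below 0 and 34 above, and of -0.44 for 11 snRNA genes, all below 0. A lower yield of short RNA in the rGO preparation may account for this. The 26 miRNA genes had a median of -0.04 (percentile 20.86). Whether their probe sets read the short mature RNA or longer precursors is not known here, so they cannot decide it. The 11 scaRNA genes, small structured RNAs themselves, had a median of -0.105 (percentile 1.24), which goes with the pattern and is no separate check. The explanation stays open. Lower transcription of the snoRNA host genes would concern the snoRNA genes alone, not the whole pattern. Only 2 SNHG host genes passed the level filter, SNHG17 at 0.22 and SNHG29 at 0.12 (median 0.17). Both stood above control, counter to this explanation, but 2 genes cannot decide it for 106, so it stays open for them. After GO the snoRNA genes had a median of 0.10 (percentile 99.99) and the miRNA genes one of -0.16 (percentile 0.08). An effect of rGO on these RNAs themselves is likewise open, as each exposure has 1 preparation.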
